A study of Homo sapiens with 6 samples.

How the data were processed

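Total RNA from 6 samples of HCT116 cells, 3 transfected with a miR-3189 mimic and 3 with a control siRNA for 48 h, was labelled with biotin and hybridised to Illumina expression BeadArrays, per the labels' protocols. Groups and replicate numbers came from the labels. The labels do not say which arm of miR-3189 the mimic carried, nor the sequence of the control siRNA.

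The deposited probe intensity values are mean bead brightness on a linear scale, written by the GenomeStudio gene expression module (1.9.0) without normalization, per the file headers. The lowest signals lay far above 0, so that no background had been subtracted. The deposited detection p-value of each probe and array is the share of the 770 negative control probes that were brighter, per the file headers and the steps of the values. The deposited bead count gives the number of beads behind each probe and array, per the file headers. A second deposited table holds log2 values that the authors processed by steps not given in the sources used here. Its values had one distribution on all arrays, with medians between 4.571 and 4.575, as quantile normalization gives. Set against the log2 signals computed here they had a correlation of 0.994 per array and a slope between 0.965 and 0.966 over probes above a log2 level of 10. Its fold changes had a correlation of 0.998 across probes, which are not independent replicates, with those computed here. The scale and direction of that table are thus known, and its background step is not. It served as an alternative only. In the control probe part of the intensity table, 72 columns name 12 arrays of 1 beadchip by position and not by sample. They could not be mapped to samples and were not used.

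Signals were background-corrected, log2-transformed and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, with negative controls inferred from the detection p-values and an offset of 16. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were tested, which left 19519 of 47231 probes. Of all probes, 43961 carried a gene symbol. Symbols were updated through the Entrez ID or accession in a RefSeq gene table of GRCh38.p14, which matched 35757 probes and changed the symbol of 8839; otherwise the array's own symbol was kept. A gene was represented by its tested probe of highest mean log2 signal, which gave 14321 genes, and 764 tested probes without a name were kept outside the gene count. Of 3558 genes with several tested probes, 69 had probes past the threshold in opposite directions. A probe not detected on any array of a group has only a bound there. The bound sets the mean of the brighter group against the mean, per array, of the lowest signal among detected probes or the probe's own signal if higher.

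Groups were compared with lmFit and eBayes of limma (two-sided, Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and a log2 fold change of at least 1 for the 2-fold count). Median SDs between arrays were 0.132 for control and 0.149 for mimic on the log2 scale, and the median SE of a fold change was 0.131. The number of arrays limits the precision. Array correlations were 0.990 to 0.994 within groups and 0.954 to 0.960 between groups. The first principal component held 79.2% of the variance and parted the groups, and the second, with 7.03%, set mimic replicates 1 (−16.03) and 3 (19.44) apart. No arrays held identical values.

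Gene lists were fixed before the data were examined, as were the tests, the alternative settings and the rule for named genes. There were 29 lists, for p53 targets, G2/M and mitosis, G1/S and DNA replication, G1 cyclins and kinases, pro-apoptotic and anti-apoptotic genes, the integrated stress response, ER chaperones, interferon response, NF-κB, cholesterol synthesis, NRF2, hypoxia, Wnt, MYC and ribosome biogenesis, cytosolic ribosomal proteins, respiratory chain, autophagy and lysosome, TGF-β, epithelial genes, mesenchymal genes, immediate early genes, small RNA machinery, DNA repair, replication-dependent histones and markers of hepatocytes, fibroblasts, blood cells and neural cells. The 26 lists with at least 5 tested members were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, adjusted over the lists. Each list was also adjusted over the list alone, gene by gene.

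Named genes are the 12 largest rises and 12 largest falls by log2 fold change among changed genes with a proper symbol, no overlap between groups and an upper group mean above the median of tested genes. They further include GDF15, CDKN1A and MDM2 whatever their values, and up to 4 members with the largest changes of each list that had at least 3 changed members or was called. From the other-cell lists with fewer, the member with the highest signal is named. Some genes that this rule selects are not reported here. Further list members with their values were named after those values were seen, namely CCNG1, DDB2, TNFRSF10B, CYFIP2, CCNE1, MCM4, DDX60, MTHFD2, PSAT1, CDH1 and APOA1, and in the closing observations KRT81, KRT86, PPP6R3, DDX19B and MKRN2.

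The alternatives were other background corrections, median scaling, the authors' table, other probe filters, the mean of a gene's probes, the replicate number as a block, eBayes with trend and robust, array weights, a stricter threshold and leaving out each sample in turn. On simulated data with 14321 genes, the fit recovered 25.4% of 67 genes shifted by 0.5, 85.1% of 67 shifted by 1 and 100% of 66 shifted by 2 on the log2 scale, with 11 unchanged genes among 151 called. Far fewer genes were shifted there than changed in the data, which makes the adjusted threshold stricter. These shares therefore do not give the sensitivity in the data. No list was called when nothing was shifted, and 1 when 1 was. Simulated genes varied independently of each other, so the list check does not test the preset correlation.

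The planned test of seed sites in 3′ UTRs needs transcript sequences and was not run. Matches to each arm's seed, with mature sequences from general knowledge, were instead searched in the 50-base probe sequences with a permutation test of 100000 resamples in Python 3.11.15 and numpy 2.4.6. Ontology terms in the array table with 10 to 500 tested genes were tested for enrichment among genes changed at least 2-fold (hypergeometric test in scipy 1.17.1, over tested genes with an annotation, 1650 tests with Benjamini-Hochberg adjustment). Both steps were tested on simulated data, where in single draws a shift of 0 put into genes with the match was found as 0.0826 (permutation p = 0.169) and a shift of −0.25 as −0.297, and 0 of 20 random draws called a term. Genes varied or were drawn independently in these checks, which therefore do not cover genes that change together. No genome build is given for the probes, and no coordinates were used.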

Results

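Transcript levels were measured in HCT116 cells, a human colorectal carcinoma line, 48 h after transfection with a miR-3189 mimic or with a control siRNA. A mimic is a synthetic RNA duplex that supplies a microRNA to the cell, and the gene for miR-3189 lies in an intron of GDF15. Each group held 3 samples, and each sample was hybridised to 1 Illumina BeadArray, which reads each 50-base probe as the mean brightness of its beads. Between 41.0% and 43.8% of the probes were detected above the negative controls on each array, with a median of 19 to 20 beads per probe, and median signals lay between 94.6 and 101.9. The stated aim was to identify the genes that miR-3189 regulates, and the comparison was therefore mimic against control siRNA. The sources do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which could be technical. All differences below are log2 fold changes, mimic minus control, with the standard error of the fit and 3 arrays per group.

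The keratin genes KRT80 and KRT7, 24 of 36 measured p53 targets and the stress genes ATF3 and GDF15 were higher in cells given the mimic, and all 32 measured genes of G2/M and mitosis were lower. The set-test calls of both lists were lost when camera ran with an estimated correlation between genes (adjusted p = 0.0751 each). For p53 targets that estimate (0.00634) was below the preset 0.01, so a higher correlation was not what removed the call. KRT80, a keratin of the intermediate filaments, rose most among the named genes (3.67 ± 0.119, SE), and KRT7, a keratin of simple epithelia, rose 7.23-fold (2.85 ± 0.113). GDF15, the host gene of miR-3189 and a secreted stress cytokine, rose 4.85-fold (2.28 ± 0.125). Large falls were those of MTND5P10, a pseudogene of a mitochondrial respiratory subunit, reported as uncertain because of its likeness to the mitochondrial transcript (−3.31 ± 0.186), and PABPC4, which encodes a cytoplasmic poly(A)-binding protein (−3.09 ± 0.134). Of 14321 genes tested, 6809 (47.5%) changed at an adjusted p under 0.05 in limma, 3502 of them upwards and 3307 downwards. The change reached 2-fold in 1247 genes, 541 up and 706 down, an excess of falls that median scaling did not show (637 up and 639 down).

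Other large rises were those of WFDC21P, a transcribed pseudogene (3.48 ± 0.148), CYSRT1 (2.73 ± 0.133) and the stress-induced transcription factor gene ATF3 (2.66 ± 0.138). MRPS35, which encodes a protein of the mitochondrial ribosome, rose by 2.40 ± 0.132, and the interferon-induced OASL rose by 2.29 ± 0.119. The kinase gene NUAK2 rose by 2.28 ± 0.164, although only 2 of its 3 control arrays detected it. GALNT5, an enzyme that starts O-linked glycosylation, rose by 2.27 ± 0.163, and the RNA-binding protein gene MSI2 rose by 2.26 ± 0.169. Among the falls, TMED10, a cargo receptor of the early secretory pathway, was 8.02-fold lower, and GNAI2, an inhibitory G protein subunit, had a log2 fold change of −2.86 ± 0.129. XXYLT1, a xylosyltransferase (−2.76 ± 0.146), LANCL1 (−2.75 ± 0.146), the endogenous retroviral envelope gene ERVMER34-1 (−2.70 ± 0.143) and PPIL1, a peptidyl-prolyl isomerase of the spliceosome (−2.57 ± 0.128), also fell. The largest limma adjusted p among the 24 genes with the largest rises and falls was 5.29e-07, for MSI2. The arrays of both groups failed to overlap in 55.1% of all genes tested, where chance gives 10%.

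**Figure D1:**
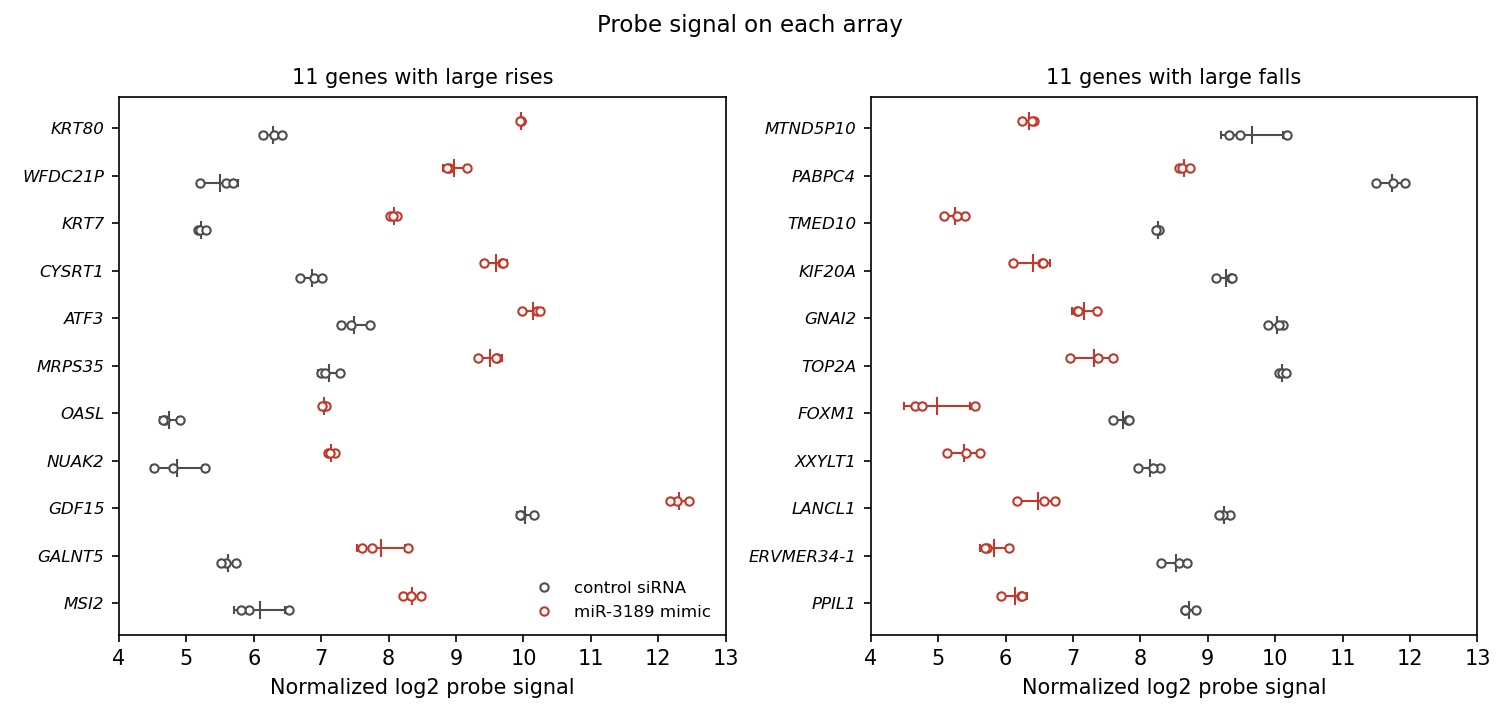
Normalized log2 probe signal of 11 genes with large rises (left) and 11 with large falls (right), on the 3 control siRNA arrays and the 3 miR-3189 mimic arrays. Circles are arrays, vertical ticks are group means and horizontal bars are SDs; the KRT80 means are 6.29 and 9.96, and the PABPC4 means are 11.73 and 8.64.

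Genes activated by p53 rose as a group. Of 36 measured p53 targets, 24 rose, 0 fell and 12 did not pass the threshold, with a median log2 fold change of 0.54 (camera adjusted p = 4.05e-06 with the preset correlation; adjusted p = 0.0751 with an estimated correlation). After GDF15, the largest rises in this list were those of TP53I3, a quinone oxidoreductase gene induced by p53 (2.14 ± 0.113), ANKRA2 (1.63 ± 0.155) and RRM2B, the p53-inducible subunit of ribonucleotide reductase (1.56 ± 0.141). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose by 1.12 ± 0.113. MDM2, the ubiquitin ligase that restrains p53, rose by 0.84 ± 0.136 from a dim control mean of 4.71. The size of the MDM2 rise ran from 0.242 to 0.954 over the 15 alternatives that tested it. CCNG1 (−0.16, adjusted p = 0.272), the DNA damage-binding gene DDB2 (−0.15, adjusted p = 0.361) and the death receptor gene TNFRSF10B (0.01, adjusted p = 0.933) were among the 12 p53 targets that did not pass. The probes of CYFIP2, counted among the risers at 0.83, disagreed, since another of its probes fell by 1.37, and the mean of its probes was −0.27 (adjusted p = 0.0696). Adjusted over the list alone, the counts were again 24 and 0.

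Transcripts of mitosis fell without exception among the members measured. All 32 genes of the G2/M and mitosis list fell, with a median of −1.53 (camera adjusted p = 1.25e-20; adjusted p = 0.0751 with an estimated correlation), and all 32 fell when adjusted over the list alone. The mitotic kinesin gene KIF20A (−2.87 ± 0.143), TOP2A, the topoisomerase of dividing cells (−2.80 ± 0.152), and CCNB2, which encodes a mitotic cyclin (−2.24 ± 0.120), were among the largest falls. FOXM1, a transcription factor that drives G2/M genes, had a log2 fold change of −2.76 ± 0.195 and was detected on 2 of the 3 mimic arrays. Of 31 genes of G1/S and DNA replication, 19 fell and 2 rose, with a median of −0.52 (camera adjusted p = 0.000244; adjusted p = 0.308 with an estimated correlation), and 19 fell and 3 rose when adjusted over the list alone. CCNE2, which encodes a G1/S cyclin (−2.04 ± 0.152), E2F2 (−1.25 ± 0.125), the thymidine kinase gene TK1 (−1.23 ± 0.136) and the flap endonuclease gene FEN1 (−1.20 ± 0.136) fell most. In the same list CCNE1, which encodes another G1/S cyclin, rose by 0.64, and the helicase subunit gene MCM4 (0.02, adjusted p = 0.926) did not pass.

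Of 18 G1 cyclins, kinases, inhibitors and pocket proteins, 8 fell and 2 rose, also when adjusted over the list alone, and the set test did not call them (adjusted p = 0.0692). CDK2 (−1.68 ± 0.129), CDK6 (−1.64 ± 0.117), the pocket protein gene RBL2 (−1.28 ± 0.113) and the inhibitor gene CDKN1C (−1.18 ± 0.158) fell, whereas CCND1, which encodes cyclin D1, rose by 1.18 ± 0.112. This list was called without control replicate 1 (adjusted p = 0.0293), within a range of 0.0293 to 0.149 over the 16 alternatives with camera's preset correlation; adjusted p was 0.308 with an estimated correlation and 0.00354 with fry. Of 22 DNA repair genes, 9 fell and 2 rose by either adjustment, with FANCI (−1.47 ± 0.126), H2AX (−1.22 ± 0.144), BLM (−1.05 ± 0.119) and FANCD2 (−0.96 ± 0.121) the largest falls. The DNA repair list missed the set test's threshold (adjusted p = 0.0530) and passed it under 6 of the 16 alternatives with the preset correlation, within a range of 0.0262 to 0.0957. These 6 were without control replicate 1 (0.0262), mimic replicate 1 (0.0465) or mimic replicate 2 (0.0486), with a replicate block (0.0458), with median scaling (0.0494) and without a filter (0.0283). Its adjusted p was 0.308 with an estimated correlation and 0.00184 with fry. Of 10 replication-dependent histone genes, 4 rose and 3 fell, or 6 and 3 when adjusted over the list alone (camera adjusted p = 0.861). H2BC12 (−1.82 ± 0.128) and H1-2 (−0.90 ± 0.139) fell, and H2BC21 (1.47 ± 0.130) and H2AC25 (0.88 ± 0.173) rose.

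Genes of the interferon response rose more often than they fell. Of 29 measured, 18 rose and 5 fell, by either the adjustment over all genes or that adjusted over the list alone, with a median of 0.54 (camera adjusted p = 0.00577; adjusted p = 0.171 with an estimated correlation). Besides OASL, the largest rises were those of IFIT1, an antiviral protein gene (1.51 ± 0.121), EIF2AK2, which encodes the double-stranded RNA sensor PKR (1.36 ± 0.121), and the ubiquitin-like modifier gene ISG15 (1.32 ± 0.136). DDX60, an antiviral helicase gene, fell by 0.90. Of 12 NF-κB and inflammatory genes, 3 rose and 1 fell by either adjustment (camera adjusted p = 0.663), namely the chemokine gene CXCL8 (1.79 ± 0.144), NFKB2 (0.86 ± 0.133) and RELB (0.55 ± 0.140) upwards and IER3 (−0.44 ± 0.128) downwards.

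Of 28 targets of the integrated stress response, 12 rose and 3 fell by either adjustment, including that adjusted over the list alone (median 0.21; camera adjusted p = 0.0303; adjusted p = 0.308 with an estimated correlation). Behind ATF3, the risers were led by SESN2, a stress-induced sestrin that also stands in the p53 list (1.27 ± 0.202), PPP1R15A, the phosphatase subunit that reverses eIF2α phosphorylation (1.22 ± 0.117), and DDIT3, which encodes CHOP (1.09 ± 0.114). In the same list MTHFD2, a mitochondrial folate enzyme gene, fell by 0.63, and the serine synthesis gene PSAT1 did not pass (adjusted p = 0.996). The call was lost without mimic replicate 3 (median 0.12, adjusted p = 0.0578). It was also lost with only probes at a detection p under 0.01 on all 6 arrays (0.136). The camera adjusted p ranged from 0.00432 to 0.136 over 16 alternatives with the preset correlation. Of 18 ER chaperones and unfolded protein response genes, 5 fell and 2 rose by either adjustment (camera adjusted p = 0.429), among them the chaperone genes HSPA5 (−0.93 ± 0.115), PDIA4 (−0.80 ± 0.127), CALR (−0.69 ± 0.122) and PDIA6 (−0.65 ± 0.116).

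Cholesterol synthesis genes rose in 14 of 24 cases and fell in 4, or in 5 when adjusted over the list alone, with a median of 0.40 (camera adjusted p = 0.0176; adjusted p = 0.217 with an estimated correlation). HMGCS1, which makes HMG-CoA (1.53 ± 0.134), and the mevalonate-phosphorylating enzymes PMVK (1.21 ± 0.136) and MVK (1.02 ± 0.140) rose, whereas INSIG1, the sterol-sensing brake on SREBP processing, fell by 0.93 ± 0.128. Of 20 NRF2 targets, 10 rose and 4 fell, or 11 and 4 when adjusted over the list alone (camera adjusted p = 0.0692). The heme oxygenase gene HMOX1 (2.11 ± 0.135), TXNRD1, a thioredoxin reductase gene (1.36 ± 0.116), and AKR1B10 (1.28 ± 0.121, detected on 2 of 3 control arrays) rose, and the sulfiredoxin gene SRXN1 fell by 1.95 ± 0.138.

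Of 23 pro-apoptotic genes, 9 rose and 4 fell, or 10 and 4 when adjusted over the list alone (camera adjusted p = 0.0692). PMAIP1, which encodes the BH3-only protein NOXA, rose by 2.14 ± 0.152, the death receptor gene TNFRSF10A by 1.14 ± 0.157, and the BH3-only genes HRK and BAD by 0.96 ± 0.126 and 0.90 ± 0.159. Of 13 anti-apoptotic genes, 3 rose and 3 fell by either adjustment, and the list had a median of 0.18 (0.05 to 0.23 over the alternatives), a mean of −0.02 and a set test in the upward direction (camera adjusted p = 0.861). BIRC5, the survivin gene, which also acts in mitosis, fell by 1.71 ± 0.117, and TNFRSF10D was at −0.55 ± 0.168, while BAG3 rose by 1.04 ± 0.15. The chosen probe of BCL2, counted among the falls, was detected on 0 of the 3 mimic arrays.

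Among the members above background, most epithelial genes rose and most mesenchymal genes fell. Of 18 epithelial and junction genes, 11 rose and 3 fell by either adjustment, including that adjusted over the list alone (median 0.60; camera adjusted p = 0.0176; adjusted p = 0.308 with an estimated correlation), led by KRT8 (1.19 ± 0.113), KRT18 (mean log2 signal 7.70 against 6.70), the epithelial transcription factor gene GRHL2 (0.96 ± 0.134) and ELF3 (0.93 ± 0.125). CDH1, which encodes E-cadherin, rose by 0.76. Of 7 mesenchymal genes measured, 6 fell by either adjustment (median −0.48; camera adjusted p = 0.0207; adjusted p = 0.308 with an estimated correlation), among them the collagen gene COL6A1 (−1.34 ± 0.121), the receptor kinase gene AXL (−0.81 ± 0.121), TWIST1 (−0.64 ± 0.136, detected on 1 of 3 mimic arrays) and VIM, the vimentin gene (−0.48 ± 0.160). The mesenchymal call was lost when every probe was tested, where the median was only −0.03 (adjusted p = 0.0516, in a range of 0.0103 to 0.0516 over 16 alternatives with the preset correlation).

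**Figure D2:**
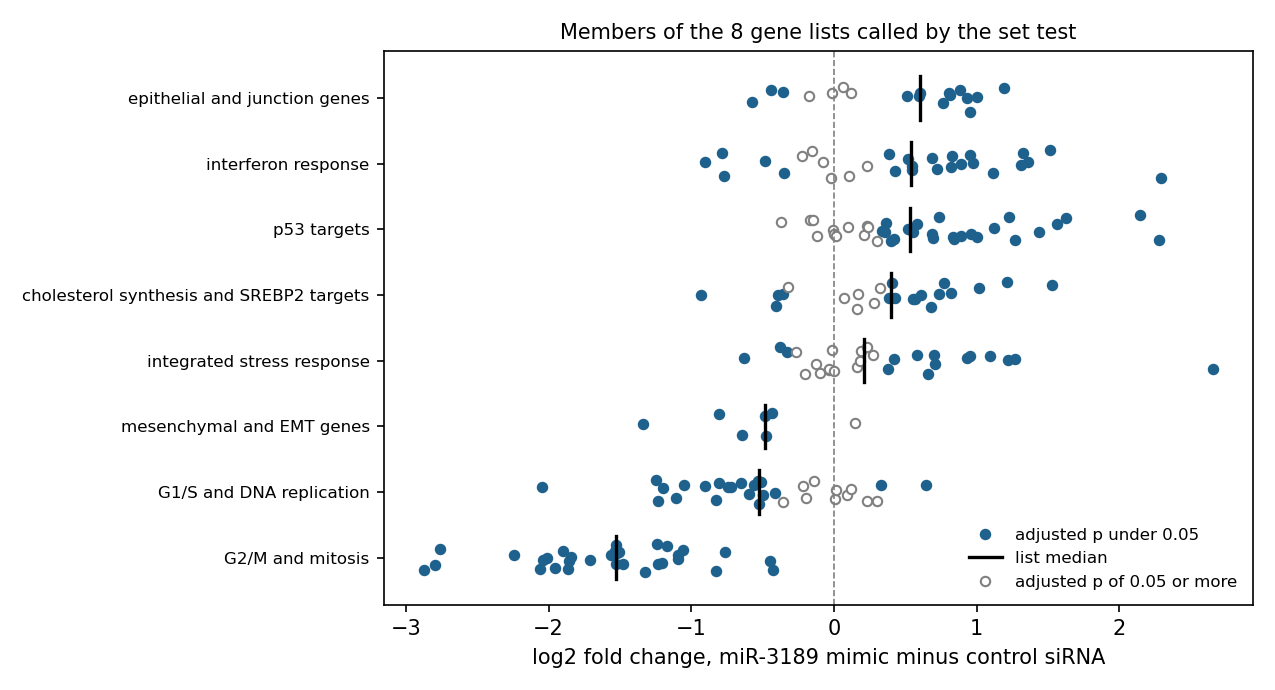
Each point is 1 member of 1 of the 8 gene lists called by camera with the preset correlation, placed at its log2 fold change (mimic minus control siRNA); filled points passed an adjusted p of 0.05, open points did not, and black bars are list medians. The medians run from −1.53 for G2/M and mitosis to 0.60 for epithelial and junction genes (0.12 when every probe was tested), and all 32 G2/M points lie below 0.

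The remaining lists were not called by the set test. Of 16 small RNA and RISC genes, 0 rose and 6 fell by either adjustment (camera adjusted p = 0.0692), among them PRKRA, a Dicer partner (−0.79 ± 0.122), TNRC6B, a scaffold of microRNA silencing (−0.62 ± 0.116), and XPO5, which exports microRNA precursors (−0.56 ± 0.114). The Argonaute gene AGO4 was not above background on any mimic array and was at least 1.37-fold lower there (adjusted p = 0.000291). Of 14 TGF-β and SMAD targets, 5 rose and 4 fell by either adjustment (camera adjusted p = 0.942), and the median of 0.03 and the mean of −0.04 differed in sign, with medians of −0.08 to 0.12 over the alternatives. ID3 (−2.25 ± 0.115), ID1 (−0.99 ± 0.120) and TGFBI (−1.06 ± 0.159, detected on 1 of 3 mimic arrays) fell, and CCN2 rose by 1.84 ± 0.131. Of 13 Wnt targets, 3 rose and 4 fell, or 4 and 4 when adjusted over the list alone (camera adjusted p = 0.832), with CD44 at −1.14 ± 0.128, EPHB2 at −0.68 ± 0.134 and RNF43 at 0.65 ± 0.120 beside CCND1. Of 21 immediate early and MAPK feedback genes, 5 rose and 4 fell by either adjustment (camera adjusted p = 0.411), with the phosphatase genes DUSP5 (1.63 ± 0.125) and DUSP1 (1.04 ± 0.136) and the AP-1 gene FOSB (1.08 ± 0.127) up and SPRY4 down (−0.84 ± 0.151).

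Of 32 cytosolic ribosomal protein genes, 24 did not pass, 6 fell and 2 rose, or 5 and 2 when adjusted over the list alone (camera adjusted p = 0.442). RPL19 (−1.33 ± 0.119), RPL14 (−0.63 ± 0.126) and RPL3 (−0.54 ± 0.135) fell and RPS7 rose by 0.77 ± 0.153, with the reservation that ribosomal protein genes have many pseudogenes of similar sequence. Of 26 MYC and ribosome biogenesis genes, 9 rose and 6 fell by either adjustment (camera adjusted p = 0.602), including WDR12 (0.97 ± 0.120) and RRP12 (0.91 ± 0.123) upwards and RRS1 (−0.94 ± 0.135) and SRM (−0.86 ± 0.125) downwards. Of 29 respiratory chain genes, 6 rose and 1 fell, or 5 and 1 when adjusted over the list alone (camera adjusted p = 0.144). NDUFB5 (1.76 ± 0.147), SDHD (0.86 ± 0.203) and UQCRB (0.60 ± 0.135) rose and UQCRC2 fell by 1.41 ± 0.155. Of 26 autophagy and lysosome genes, 7 rose and 7 fell, or 9 and 8 when adjusted over the list alone (camera adjusted p = 0.832), with the lysosomal protease genes TPP1 (−1.85 ± 0.126) and CTSB (−1.21 ± 0.182) down and ATG16L1 (1.15 ± 0.116) and CTSL (0.90 ± 0.131) up. Of 24 hypoxia and glycolysis genes, 5 rose and 3 fell by either adjustment (camera adjusted p = 0.861), among them ANKRD37 (1.26 ± 0.211), PFKP (0.48 ± 0.119) and VEGFA (0.47 ± 0.140) upwards and BNIP3 (−0.62 ± 0.152) downwards.

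Markers of other cell types were mostly undetected, and those measured moved in both directions. Of 13 hepatocyte markers 3 were tested, and ALB rose by 0.43 ± 0.162 (adjusted p = 0.0442). APOA1 was higher as well (0.68), but its probe was not above background on any control array, so this size is uncertain. It ran from 0.216 to 0.956 over the 12 alternatives that tested it. COL1A1, the 1 fibroblast marker tested of 10 and a member of the mesenchymal list as well, fell by 0.43 ± 0.133. Of 6 blood cell markers tested of 13, CD14 rose by 0.77 ± 0.135, and HBG1 (−0.59 ± 0.117) and CORO1A (−0.46 ± 0.130, detected on 1 of 3 mimic arrays) fell (camera adjusted p = 0.869). TUBB3, 1 of 2 neural markers tested of 10, fell by 0.39 ± 0.126. Adjusted over each list alone the calls were the same in number.

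Several of these smaller changes lost their call under some alternative. ALB lost it under 9 of 16 alternatives, with adjusted p between 0.00948 and 0.161, including without control replicates 1 (0.140) and 3 (0.161) and without mimic replicates 1 (0.142) and 2 (0.110). VIM lost it without control replicates 1 (0.0592) and 2 (0.0679) and without mimic replicate 1, where its log2 fold change was −0.28 (0.0969), within a range of 0.00596 to 0.0969. TUBB3 lost it without control replicates 1 (0.0700) and 2 (0.0520) and without mimic replicate 3 (0.0756), within a range of 0.00333 to 0.15. TNFRSF10D lost it without control replicate 1 (0.0779) and mimic replicate 1 (0.0615), within a range of 0.00410 to 0.0779, and VEGFA without control replicate 3 (0.0602) and mimic replicate 1 (0.05), within a range of 0.00278 to 0.0602. Without control replicate 1, IER3 (0.0604, range 0.000497 to 0.0604) and COL1A1 (0.0807, range 0.00846 to 0.0807) no longer passed, and CORO1A lost its call with no background correction (0.0914, range 0.00207 to 0.0914).

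With an estimated correlation in camera, none of the 8 list calls held, so that 0 lists were called, and fry, which tests each list on its own, called 18 of 26. The estimates were below the preset 0.01 for p53 targets (0.00634), the interferon response (−0.00822) and cholesterol synthesis (−0.0357). A higher correlation therefore does not account for the loss of those calls. The other called lists had estimates above 0.01, up to 0.185 for mesenchymal genes. Because calls were also lost where the estimate was lower, their losses cannot be put down to a higher correlation alone. The 2-fold count depended on the background correction, with 388 genes when none was applied and 578 with normexp without control probes at an offset of 50, against 1247. Without background correction the medians of called lists also moved by over 1.5 times, to 0.18 for the interferon response, 0.31 for p53 targets, −0.33 for G1/S and DNA replication and −0.18 for mesenchymal genes, and with normexp to 0.27 for the interferon response and −0.29 for mesenchymal genes. Of 135 changed genes in the named set, 53 had a log2 fold change that moved by over 1.5 times without background correction and 26 with normexp. The 22 largest changes shrank in this way in 11 genes without background correction, namely WFDC21P (to 2.10), KRT7 (1.48), OASL (0.91), NUAK2 (0.94), GALNT5 (1.22), MSI2 (1.37), TMED10 (−1.60), FOXM1 (−1.30), XXYLT1 (−1.48), ERVMER34-1 (−1.62) and PPIL1 (−1.65). With normexp the same held for OASL (1.30), NUAK2 (1.33) and FOXM1 (−1.74), and with a gene as the mean of its probes for OASL (1.35) and MSI2 (1.31).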

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

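Probes that carry no gene name took no part in the gene comparison, and a signal there was looked at again because it stood above the level in the control arrays. Of 764 such probes tested, 207 passed a limma adjusted p under 0.05, with 104 higher and 103 lower with the mimic. This is a smaller share than the 47.5% of tested genes that changed. No explanation was tested for them.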

How the results depend on the processing

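All alternatives in this part were chosen before the data were examined. The count of changed genes stayed within 1.5 times of 6809 under each alternative run, from 4876 at an adjusted p under 0.01 to 7315 with array weights. Leaving out 1 sample at a time gave 5729 to 6542 changed genes, 1195 to 1302 genes changed at least 2-fold and 7 to 10 lists called. The 2-fold count moved from 1247 to 388 with no background correction and to 578 with normexp without control probes at an offset of 50, which changed the method and the offset together. The 8 list calls became 0 with an estimated correlation (smallest adjusted p 0.0751) and 18 with fry, which does not set a list against other genes. The replicate numbers did not pair the samples, since deviations of equally numbered arrays correlated at −0.0716, 0.00236 and 0.00393; a replicate block gave 6693 changed genes, 1247 at least 2-fold and 9 lists. Median scaling gave 6863 changed genes, of which 56.0% rose against 51.4%, and the authors' values gave 6707, of which 6654 were the same genes. Leaving aside the estimated correlation and fry, lists kept their side of the threshold in 401 cases, lost it in 3 and gained it in 11. Named genes, 140 in all, kept it in 2187 cases and lost it in 25, in 8 genes; 1 reversed, CYFIP2, at −0.27 (adjusted p 0.0696) with a gene as the mean of its probes, because its probes moved in opposite directions. Without a filter the pro-apoptotic (adjusted p 0.0263), NRF2 (0.0263), respiratory chain (0.0225), small RNA (0.00785) and DNA repair (0.0283) lists were also called. Over the 16 alternatives with the preset correlation the adjusted p of the first 4 reached 0.149, 0.383, 0.298 and 0.182, and with an estimated correlation 0.308, 0.308, 0.358 and 0.308. Signal over background limits dim probes, whose fold changes are compressed. Not run were a beadchip block, since no column ties a sample to a chip position, and the 3′ UTR seed-site test with its alternatives.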

Other observations

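The enrichment tests, the test under median scaling, the tests of 6-mer and 8-mer matches, those of 6-mer and 7-mer matches apart from the longer match, the test of shares, the ranking by standardized difference and the reading of the rank within 1 SE were chosen after results had been seen. Among genes that rose at least 2-fold, 1 ontology term of the array table was enriched, the keratin filament, with 5 of its 11 tested genes against 0.445 by chance (adjusted p = 0.00818 over 1650 tests). These were KRT80, KRT7, KRT81 (2.42), KRT86 (1.28 ± 0.125, SE) and KRT8, all higher on each of the 3 mimic arrays than on any control array. The probe of KRT81 was not above background on any control array, so the size of its rise is uncertain. Its log2 fold change ran from 0.905 to 2.51 over the 12 alternatives that tested it. That of KRT86 ran from 0.399 to 1.35 over 15 alternatives, so both genes were below 2-fold under some setting. The enrichment counts KRT81 and KRT86 separately and was run under the main settings only. These 2 genes are close paralogs and are reported as uncertain. Among genes that fell at least 2-fold, cell division (49 of 171 genes against 9.60 by chance, adjusted p = 1.71e-19) and mitosis (43 of 131 against 7.36, adjusted p = 1.71e-19) led. The phosphoinositide signalling term was enriched as well (8 of 26 against 1.46, adjusted p = 0.00987), but its fallen members AURKA, FEN1, HMGB2, NDC80, SPAG5, TOP2A and UBE2C are known for mitosis, DNA repair or chromatin, and only PIK3CB encodes a lipid kinase.

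Nearly as many genes changed as did not. Of the 10 splits of the 6 arrays into 3 and 3, only 1 gave as many as 6809 genes, the real split. The highest of the other splits gave 0. Each of those mixes mimic and control arrays, so the group difference counts as spread there and low counts were largely fixed in advance. The splits are also too few for a share under 0.05, so they do not decide whether the count came by chance. Quantile normalization as the source of the count is argued against by median scaling, which called 6863 genes. Median scaling also gives the arrays one common centre, so the comparison does not test that step. An effect of the control siRNA itself, for which no untreated cells were measured, and secondary responses to the first genes changed stay open and were not tested.

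Genes whose 50-base probe holds the 7-base match to the seed of miR-3189-3p (CCCAAGG) were lower than other genes by a mean log2 fold change of −0.168 (102 of 14321 genes, permutation p = 0.0040, adjusted p = 0.020 over 10 matches), and 36.3% of them fell against 23.0% of the other genes (two-sided Fisher's exact p = 0.0029, adjusted p = 0.012 over 4 tests), while 17.6% rose against 24.5% (Fisher's exact p = 0.13). PPP6R3 (−1.77), DDX19B (−1.61) and MKRN2 (−1.59) were the lowest. Probe GC content is argued against, since the difference was −0.157 among genes of like GC content (permutation p = 0.0069), and genes with the match to the 5p seed were higher by 0.0388 (permutation p = 0.58, 69 genes). The prediction written beforehand asked for a rank within the lowest 1% of 14139 heptamers as support and took a rank outside the lowest 5% as evidence against the 3p seed. The rank was 985 (6.97%), and a difference 1 SE (0.0620) lower would rank 419 (2.96%) and 1 SE higher 2136 (15.1%). Support was thus missed even at 1 SE lower. The criterion against the seed was met, though by less than 1 SE. Heptamers ranked as low by the raw difference were held by a median of 19 genes, against 102 for the seed, and small sets vary more. The rank by standardized difference, 70 (0.5%), or 104 (0.74%) against like GC content, was not the measure predicted and is not counted as support. Repression through the 3p seed stays a candidate explanation. By that prediction these probe sequences do not support it, and the criterion against it was narrowly met. They do not exclude it, since a probe covers a small part of a transcript. All genes with the 3p 6-mer differed by −0.13 (382 genes, permutation p = 4e-05, adjusted p = 0.0004 over 10 matches) and those with the 8-mer by −0.27 (34 genes, permutation p = 0.0067, adjusted p = 0.022), but these sets overlap with the 7-mer set and are not separate evidence. The 7-mer read backwards (−0.0559, permutation p = 0.46) and its reverse complement (−0.0233, permutation p = 0.68) gave no difference past the threshold. Against genes with no 6-mer match and without regard to GC content, the difference was −0.117 for genes with the 6-mer but not the 7-mer (280 genes, permutation p = 0.00089, adjusted p = 0.0036 over 4 tests) and −0.117 for the 7-mer but not the 8-mer (68 genes, permutation p = 0.095, adjusted p = 0.19). For the 5p seed, all genes with the 6-mer differed by 0.031 (349 genes, permutation p = 0.33). Those with the 5p 8-mer differed by 0.31, upwards (18 genes, permutation p = 0.025, adjusted p = 0.062).

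In 69 genes, probes passed the threshold in opposite directions. A probe that the array table marks as isoform-specific was present in 71.0% of them, against 34.3% of the other 3489 genes with several tested probes (two-sided Fisher's exact p = 8.61e-10), which is consistent with a shift between transcript isoforms, as a hypothesis. The shares were not matched for the number of probes per gene, and genes with more probes have more chances of both features. Small shifts of noisy probes stay open for part of these genes, since both probes shifted by at least 0.5 in only 33.3% of them. Both shifts reached 1 in 2 genes, chosen after their values were seen: ANTXR1 (1.31 ± 0.141 and −1.12 ± 0.145) and RO60 (1.04 ± 0.167 and −2.27 ± 0.131).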
